A study of Sus scrofa with 6 samples.

How the data were processed

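Strand-specific, rRNA-depleted total RNA libraries of 4 pgEpiSC samples (E10 embryonic epiblast) and 2 pEF samples (E30 fetal fibroblasts) of Sus scrofa were sequenced on an Illumina HiSeq instrument, per the labels' protocols. The labels give an average of 127.83 M raw and 126.01 M high-quality 150-bp paired-end reads over the libraries, and no depth for a single library. STAR 2.6.0c and kallisto 0.44.0 are named in the submitters' processing notes; the role of each, the genome build and the annotation are not given in the sources used here. The values deposited by the authors are TPM, per the file headers, with 1 column per library and 1 row per Ensembl gene (20132 rows). The columns sum to between 93556 and 320206 TPM. Depth per library could not be recovered from TPM, so no intervals from read sampling are given.

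Gene IDs were paired with symbols by the gene name table; 14062 of 20132 rows (69.8%) matched and 6070 did not. The 2 rows that shared a symbol were summed, which left 20131 genes. Genes that matched no row by symbol were not analysed here. Genes with TPM of at least 1 in at least 2 libraries were tested (10424 genes, 8917 with a symbol). Values were put on the scale log2(TPM + 1) as deposited and fitted in limma 3.58.1 (R 4.3.3) with group as the factor and an empirical Bayes variance with a trend. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, over all tested genes. Library measures were compared by exact two-sided permutation over the 15 splits of 4 against 2, where the smallest p is 0.0667. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

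The 29 gene lists were fixed before any value was seen. Lists with at least 5 tested members (25) were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were run beside it. The remaining 4 lists (germline, endothelial, blood and immune, and Y-linked genes with XIST) had too few tested members, and 0 members of the last were in the table. The genes named in the text follow a rule fixed at the same time. It takes the 8 largest increases and the 8 largest decreases among called genes with a symbol, groups that do not overlap and a mean of at least 10 TPM in the higher group. It adds up to 4 called members of each list by absolute fold, at most 2 members that moved against their list, any member of the core, naive and formative or primed lists, and the 3 most abundant genes of each group. Some genes that this rule takes are not reported here. Calls rest on a fold, a standard error and an adjusted p from limma; medians of lists are given less the median of all tested genes.

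The fit was tested on simulated data with 200 genes of known change among 10424. As deposited, 0, 72, 100 and 96% of genes raised by 1, 2, 3 and 4 log2 units were recovered (25 genes each) and 0, 16, 84 and 100% of those lowered by as much, 117 of 200 in all, with 10 unchanged genes called. After median-ratio scaling 56, 92, 100 and 96% and 52, 88, 96 and 100% were recovered, 170 of 200 in all, also with 10 unchanged genes called. A simulated shifted set had a camera p of 6.51e-35, and 7 of 100 unshifted sets had a p below 0.05. The simulated noise was independent between genes, so these sets do not show how the preset correlation performs on the data. In this simulation changes of 1 log2 unit were thus not recovered by the fit of the values as deposited. Far fewer genes were changed than were called in the data, which makes the adjusted threshold stricter. In the data some calls were smaller, as 1836 of 1874 higher and 974 of 983 lower calls reached 1 log2 unit. The simulated values were built from scaled values and the library factors, so better recovery after scaling was built in.

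The alternatives tried were pseudocounts of 0.1 and 5; no filter and a filter of mean TPM of at least 5; median-ratio scaling, rescaling to 1000000, quantile normalization, and leaving out histone and ribosomal protein genes before rescaling; an empirical Bayes variance without trend and a robust one; library weights; a replicate block; camera with an estimated correlation; detection at 0.1 and 5 TPM; Spearman correlation; and each library left out in turn. Median-ratio scaling combined with each library left out, with the replicate block and with the estimated correlation, and scaled marker and detection counts, were chosen after seeing the data. 0 mitochondrial symbols were in the table, so a mitochondrial share was not analysed here.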

Results

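Strand-specific RNA-seq of rRNA-depleted total RNA was used to compare 2 kinds of pig cells. The first were pgEpiSC, stem cells of the pre-gastrulation epiblast that came from the epiblast of embryos at embryonic day 10. The second were pEF, porcine embryonic fibroblasts taken from fetuses at embryonic day 30, a differentiated mesenchymal cell type. The series held 4 pgEpiSC libraries and 2 pEF libraries, described as biological replicates. Expression was given as TPM for 20132 genes, of which 14062 (69.8%) had a symbol. The listed genes summed to between 157288 and 320206 TPM in the pgEpiSC libraries and to 93556 and 145611 TPM in the pEF libraries, far short of 1000000; what made up the rest was not analysed here. TPM keeps no read depth, and the depth of each library is unknown here. Genes at 1 TPM or more numbered 7149, 10250, 9892 and 7146 in pgEpiSC libraries 1 to 4 and 7208 and 8699 in pEF libraries 1 and 2. The group means, 8609 ± 1694 (SD, n = 4) and 7954 ± 1054 (SD, n = 2), were not told apart (exact two-sided permutation test, p = 0.6, where 15 splits allow no p below 0.0667). After median-ratio scaling the counts were 8094, 8384, 8498 and 8046 against 8660 and 8804, so the order of the 2 means turned (difference -476.5, exact permutation p = 0.133). The 47 ribosomal protein genes found by symbol held 13.5 ± 1.87% of the listed TPM in pgEpiSC and 10.5 ± 1.11% in pEF (exact permutation p = 0.133). The 4 histone genes found by symbol held 0.382 ± 0.0649% and 0.187 ± 0.00319% (exact permutation p = 0.0667, the smallest these 15 splits allow). Any such genes with no symbol are left out of these shares. Genes with no symbol held 40.9 ± 3.61% and 23.0 ± 0.0970% of the listed TPM.

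**Figure D1:**
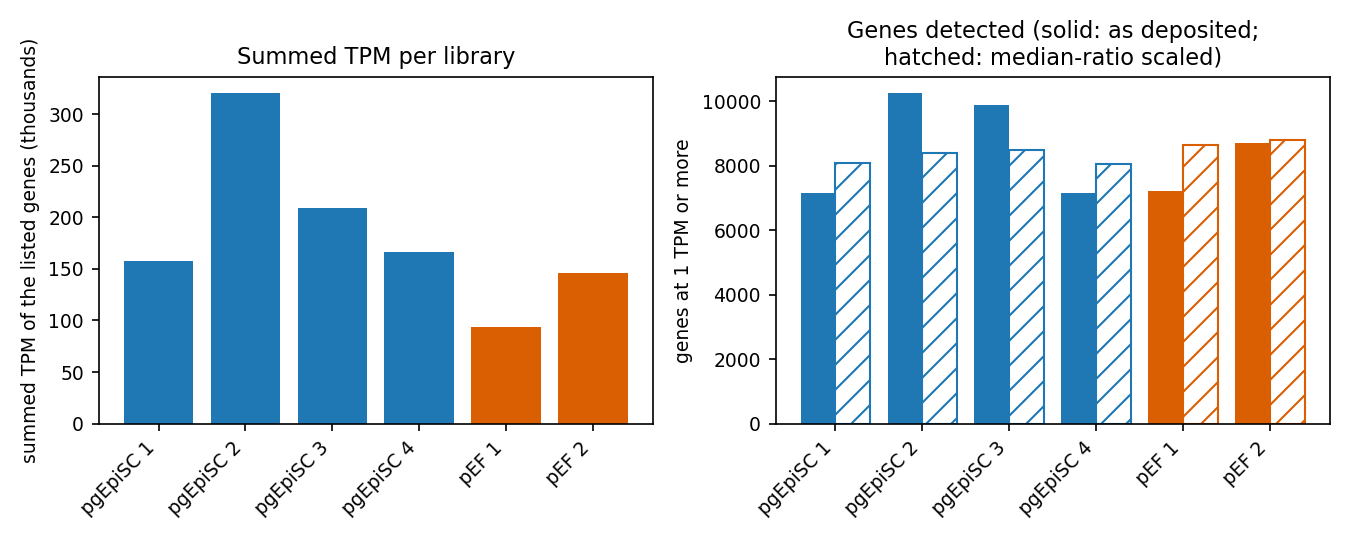
Summed TPM of the listed genes (left) and genes at 1 TPM or more (right; solid as deposited, hatched after median-ratio scaling) in 4 pgEpiSC (blue) and 2 pEF (orange) libraries. Detected genes ranged from 7146 to 10250 as deposited and from 8046 to 8804 after scaling.

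The question set by the design was how the transcriptome of pgEpiSC differs from that of fibroblasts. The lists of core pluripotency factors, epithelial junctions, cell cycle and DNA replication, and DNA methylation were called higher in pgEpiSC, whereas those of the extracellular matrix, the contractile apparatus, mesenchymal transcription factors and the interferon response were called lower. These 8 list calls rest on camera with a preset correlation (adjusted p from 1.07e-33 to 0.00943), and not 1 of them holds with an estimated correlation (adjusted p from 0.112 to 0.662). The named genes with the largest increases included LIN28A, an RNA-binding protein that restrains let-7 maturation, at 435 ± 294 TPM in pgEpiSC (SD, n = 4) and listed at 0 in both pEF libraries. LEFTY2, a secreted Nodal antagonist, was at 193 ± 114 against 0.02003 ± 0.00644 TPM (pEF, SD, n = 2). DNMT3B, a de novo DNA methyltransferase, was at 263 ± 254 against 0.220 ± 0.206 TPM. APOE, a lipid carrier, the keratins KRT8 and KRT18, the homeobox factor NANOG and the adhesion molecule EPCAM completed the 8 largest increases, with APOE at 164 ± 80.1 against 0.776 ± 0.180 TPM and log2 folds of 6.04 ± 0.54 (SE), 5.37 ± 0.59, 5.72 ± 0.53 and 5.30 ± 0.57 for the others. The largest decreases were those of CCL2, a chemokine, at 0.0342 ± 0.0308 against 666 ± 10.3 TPM, and ACTA2, smooth muscle actin, at 0.860 ± 0.428 against 1243 ± 1086 TPM. COL3A1, THBS1, COL1A2, AMCF-II, ACTG2 and ASPN followed, with log2 folds between -7.70 for COL3A1 and -6.52 for ASPN.

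Of 10424 genes tested with limma on log2(TPM + 1), 1874 were higher and 983 lower in pgEpiSC at a Benjamini-Hochberg adjusted p below 0.05, 1836 and 974 of them by at least 1 log2 unit. The 2 groups of libraries did not overlap for 5165 genes (49.5%, where chance gives 13.3%). The split depended on scale. The median log2 fold of all tested genes was 0.48 as deposited and 0.02 after median-ratio scaling, and the share of calls that were higher was 65.6% as deposited (1874 against 983) and 46.6% after scaling (2810 against 3222). All 983 lower calls and 1687 of the 1874 higher calls were also made after scaling, and 0 genes were called in opposite directions. For this reason list medians below are given relative to the all-gene median, and single genes carry the fold of the values as deposited, on the log2(TPM + 1) scale, which understates the change of low genes. Without pEF replicate 1 the counts fell to 252 higher and 681 lower, without pEF replicate 2 to 590 and 555, and without pgEpiSC replicate 3 to 1057 and 794. With 1 pEF library left, that lone library is assumed to vary like the pgEpiSC group.

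**Figure D2:**
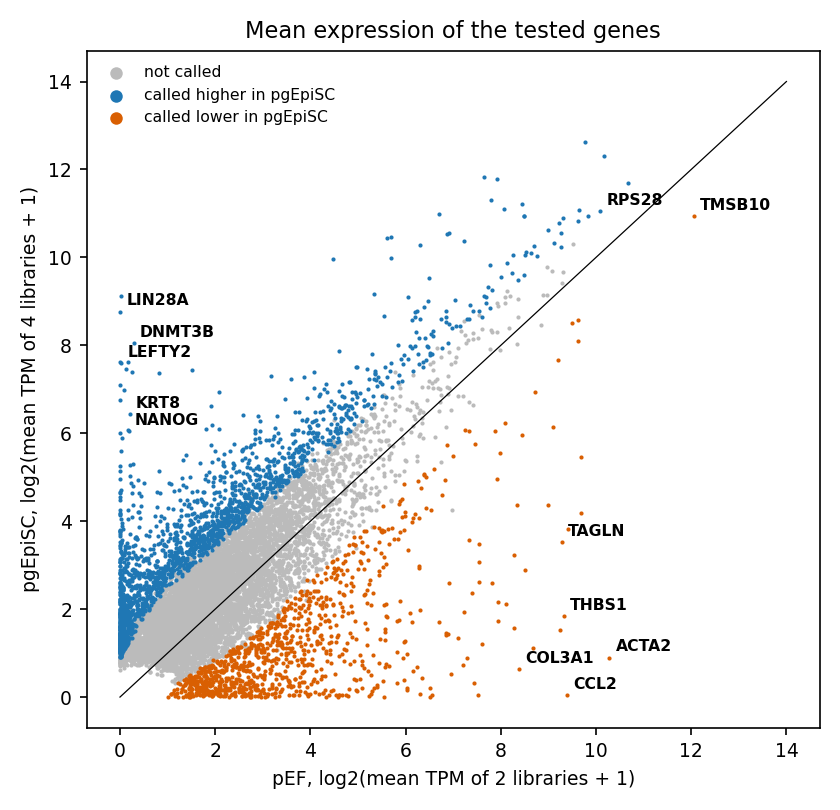
Mean expression of the 10424 tested genes as log2(mean TPM + 1), with pEF (2 libraries) on the x axis and pgEpiSC (4 libraries) on the y axis. Blue points are the 1874 genes called higher and orange points the 983 called lower in pgEpiSC; the line marks equal means.

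Some of the most abundant named genes were shared by the 2 groups. RPS28, which encodes a ribosomal protein, and TMSB10, an actin-binding thymosin, were among the most abundant in pgEpiSC at 2134 ± 440.2 and 1965 ± 146 TPM. TMSB10, ACTA2 and RPS28 led in pEF, where TMSB10 reached 4246 ± 2667 and RPS28 1087 ± 73.6 TPM. RPS28 was called higher as deposited (0.95 ± 0.35, adjusted p = 0.0370), was not called after scaling (0.30) and was lower after quantile normalization (-0.63). TMSB10 was lower (-0.96 ± 0.36, adjusted p = 0.0398), a call lost without pEF replicate 2 (-0.27, adjusted p = 0.687). The calls of RPS28 and TMSB10 were also lost without pgEpiSC replicate 1, 3 or 4, at adjusted p = 0.109, 0.0741 and 0.0602 for RPS28 and 0.0818, 0.0804 and 0.0601 for TMSB10, and RPS28 with either pEF library left out, at 0.88 and 1.02.

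The tested core pluripotency factors were higher in pgEpiSC, a direction that the filter set. No gene of the list exceeded 0.247 TPM in a pEF library, so each tested member passed the filter through pgEpiSC alone. The filter also left out the list genes that were low in both groups, so it favoured large folds. It set no upper limit to them. The list median and its camera p are thus no independent support for the direction. All 8 tested members rose, also 8 when adjusted over the list alone, with a median 2.55 log2 units above that of all genes (camera with a preset correlation, adjusted p = 1.34e-08; adjusted p = 0.285 with an estimated correlation). NANOG reached 65.01 ± 37.9 TPM against 0.135 ± 0.159 in pEF. TRIM71, a let-7 target and ubiquitin ligase, and PRDM14, a repressor of differentiation genes, were at 16.8 ± 13.8 and 9.95 ± 6.19 TPM and listed at 0 in both pEF libraries, as were ZSCAN10 and GDF3 (4.87 ± 4.44 and 6.06 ± 5.02 TPM in pgEpiSC). LIN28B and NODAL were at 6.96 ± 3.76 and 5.06 ± 2.04 TPM. FGF4 and DPPA2 stayed under 1 TPM in both groups. Of the 18 genes of the list, 10 had a symbol match, and POU5F1 and SOX2 were among those not analysed here. The calls of GDF3, NODAL and ZSCAN10 were lost with either pEF library left out, at folds of 2.56, 2.52 and 2.28 without replicate 1 and 2.56, 2.53 and 2.28 without replicate 2, and that of LIN28B without replicate 1 (2.74); 4 members were called without pEF replicate 1 and 5 without replicate 2.

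Genes of formative and primed epiblast were mostly higher, and those of the naive state were mostly low. Of 18 tested formative and primed members, 11 rose, 3 fell and 4 were not called (12, 3 and 3 adjusted over the list alone), with a relative median of 1.11 (adjusted p = 0.00151; adjusted p = 0.662 with an estimated correlation). All 18 averaged at least 1 TPM in pgEpiSC and 7 at least 10 TPM. Besides LEFTY2 and DNMT3B, OTX2, a homeobox factor of the epiblast and anterior neural plate, was at 24.00 ± 7.88 against 0.00158 ± 0.00223 TPM, and SALL2, a zinc finger factor, at 24.98 ± 17.6 against 1.37 ± 0.402 TPM. SFRP1 and SFRP2, secreted WNT antagonists, and the growth factor FGF2 fell, FGF2 from 21.1 ± 13.2 TPM in pEF to 3.24 ± 2.18 TPM; without pEF replicate 1 the folds of SFRP1, SFRP2 and FGF2 were -0.54, -2.10 and -1.73 and no longer called, and without pEF replicate 2 that of SFRP2 was -1.59 and not called. Members higher and lower numbered 4 and 0 without pEF replicate 1 and 5 and 2 without replicate 2. Of the 15 naive members in the table, 10 were under 1 TPM in both groups, among them ESRRB (0.356 ± 0.185 TPM in pgEpiSC), DPPA5 (0.198 ± 0.106), TBX3 (0.0175 ± 0.00606) and KLF17 (0.00494 ± 0.00987). The 5 tested members gave no call for the list (relative median -1.73, adjusted p = 0.182): KLF2 and KLF4 fell, from 2.42 ± 0.750 and 2.84 ± 0.722 TPM in pEF to 0.256 ± 0.135 and 0.609 ± 0.173 TPM, and KLF5, FGFR4 and STAT3 were not called (0 higher at this threshold and 1 higher, 3 lower adjusted over the list alone). After scaling all 3 were called, KLF5 and FGFR4 higher (0.53 and 0.74) and STAT3 lower (-1.86), with the list still not called (adjusted p = 0.307). As deposited FGFR4 was called higher without pgEpiSC replicate 1 or 4 (1.13 and 1.15) and STAT3 lower without pgEpiSC replicate 2 (-1.57). KLF4 lost its call without pgEpiSC replicate 3 or 4 (-1.24 and -1.18) or pEF replicate 2 (-1.06), which left 1 naive member called lower each time.

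**Figure D3:**
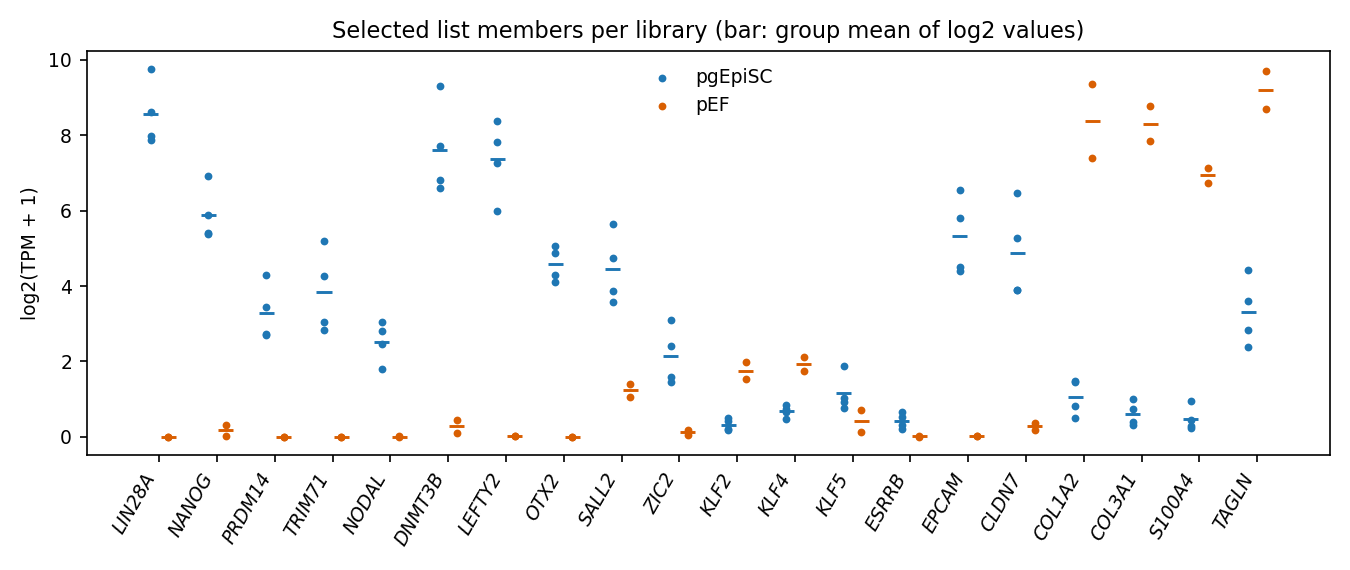
Values of 20 list members as log2(TPM + 1), 1 point per library, for pgEpiSC (blue, 4 libraries) and pEF (orange, 2 libraries); bars are group means of the log2 values. LIN28A lies at 0 in both pEF libraries, and naive members such as KLF2 and ESRRB lie below 1 TPM in all 4 pgEpiSC libraries.

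The 2 cell types differed along the epithelial and mesenchymal axis. Of 21 tested genes of epithelial junctions and adhesion, 18 rose, 0 fell and 3 were not called (20, 0 and 1 adjusted over the list alone; relative median 2.30, adjusted p = 1.42e-09; adjusted p = 0.560 with an estimated correlation). EPCAM was at 47.5 ± 34.3 against 0.0118 ± 0.00156 TPM, CDH1 (E-cadherin) at 25.3 ± 21.8 against 0.0209 ± 0.0184 TPM, the tight junction gene CLDN7 at 38.3 ± 34.7 against 0.217 ± 0.119 TPM and SPINT2, a serine protease inhibitor, at 28.1 ± 18.8 against 0.417 ± 0.0934 TPM. All 21 tested genes of fibroblasts and extracellular matrix fell (21 adjusted over the list alone; relative median -4.50, adjusted p = 1.07e-33; adjusted p = 0.112 with an estimated correlation). The fibrillar collagens COL3A1, COL1A2 and COL5A2 were at 0.560 ± 0.358, 1.17 ± 0.687 and 1.31 ± 0.692 TPM in pgEpiSC and at 335 ± 151, 409 ± 342 and 195 ± 130.4 TPM in pEF, and S100A4 at 0.428 ± 0.352 against 123 ± 23.98 TPM. Of 11 contractile and muscle genes, 10 fell and 1 was not called (11 and 0 adjusted over the list alone; relative median -5.54, adjusted p = 3.67e-23; adjusted p = 0.145 with an estimated correlation), with the actin-binding TAGLN at 10.5 ± 7.31 against 623 ± 296 TPM and the tropomyosin TPM1 at 13.1 ± 5.03 against 685 ± 489 TPM. Of 7 mesenchymal transcription factors, 6 fell and 1 was not called (the same counts adjusted over the list alone; relative median -2.93, adjusted p = 1.42e-09; adjusted p = 0.112 with an estimated correlation). Of the 21 such factors in the table, 1 averaged 1 TPM or more in pgEpiSC and 10 did in pEF. Here too the filter favoured members that are lower in pgEpiSC. PRRX2, PRRX1 and ZEB1, a repressor of E-cadherin, had log2 folds of -5.78 ± 0.56, -4.71 ± 0.56 and -2.45 ± 0.44. Of the 34 HOX genes in the table, 6 passed the filter, 5 of which fell and 1 of which was not called (the same adjusted over the list alone; relative median -1.85, adjusted p = 6.52e-05; adjusted p = 0.112 with an estimated correlation). Of the HOX genes 0 averaged 1 TPM or more in pgEpiSC and 9 did in pEF, so the filter favoured members that are lower in pgEpiSC. HOXA10 was at 0.122 ± 0.122 against 3.93 ± 0.0418 TPM, and HOXC8, HOXD8 and HOXA9 had folds of -1.65 ± 0.33, -1.38 ± 0.32 and -1.35 ± 0.30. Of the epithelial members 5 were called without pEF replicate 1 and 8 without replicate 2.

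**Figure D4:**
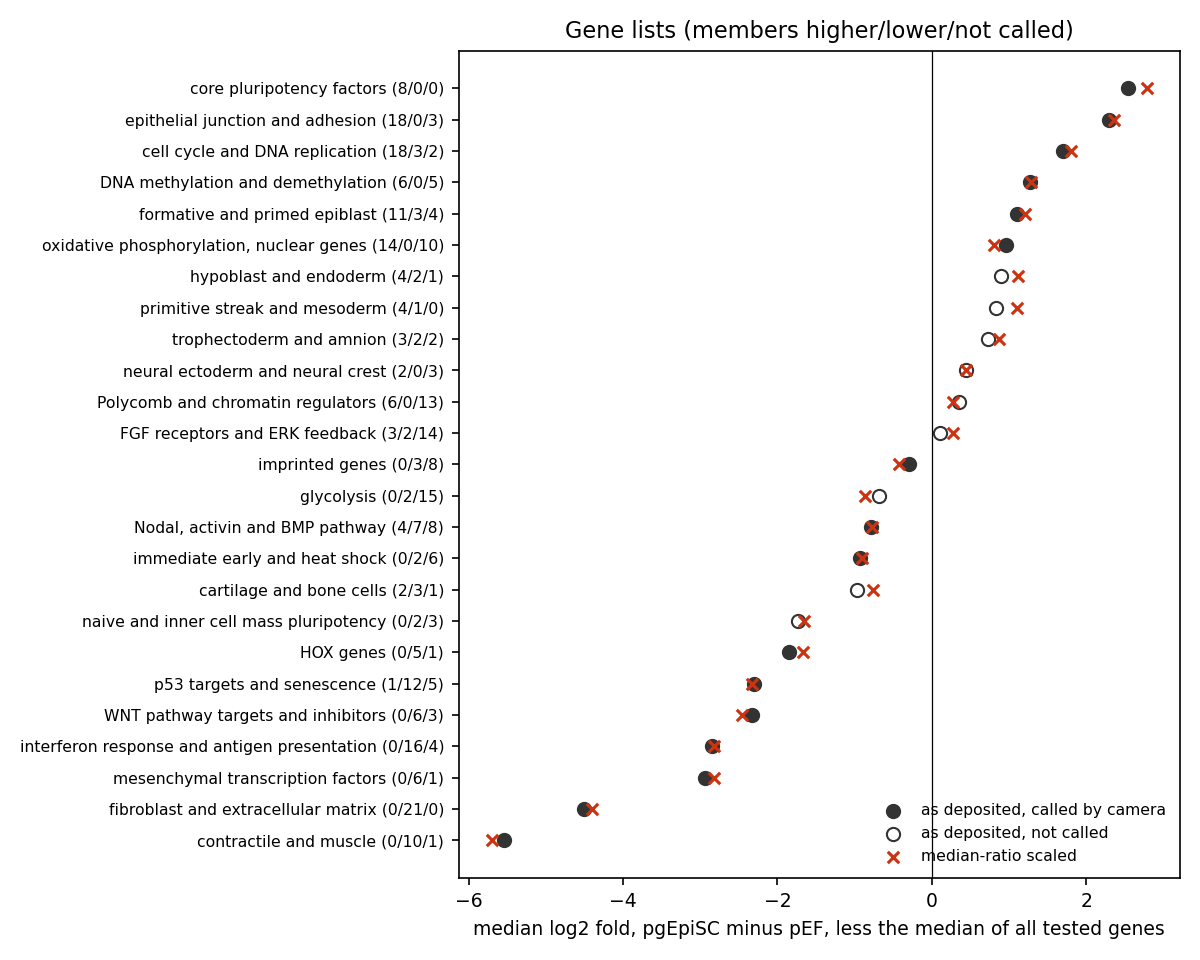
Median log2 fold (pgEpiSC minus pEF) of the 25 tested gene lists, less the median of all tested genes, as deposited (circles, filled where called by camera with a preset correlation) and after median-ratio scaling (crosses). Labels give members higher, lower and not called, and the medians run from -5.54 (contractile and muscle) to 2.55 (core pluripotency factors) as deposited.

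No tested list of another lineage was called by camera as deposited, and most genes of each were below the filter. Of the 18 primitive streak and mesoderm genes in the table, 13 were below 1 TPM in both groups. GSC, WNT3, EOMES and WNT8A passed the filter through pgEpiSC alone, and MESP2 through pEF alone. The filter thus set the directions of these 5. Of the 5 tested, 4 rose and 1 fell (the same adjusted over the list alone; list not called, adjusted p = 0.218): GSC was at 3.74 ± 1.57 TPM, WNT3 at 1.72 ± 1.16, EOMES at 1.62 ± 0.716 and WNT8A at 1.41 ± 0.401 TPM in pgEpiSC, while MESP2 was higher in pEF. None of these 5 calls held without pEF replicate 1, where the folds were 1.86, 1.29, 1.32, 1.25 and -0.74. Without pEF replicate 2 those of GSC, WNT3, EOMES and WNT8A were 1.92, 1.33, 1.34 and 1.24 and not called, and MESP2 was not called without pgEpiSC replicate 1, 3 or 4 (-0.84, -0.91 and -0.85). Among hypoblast and endoderm genes 4 rose, 2 fell and 1 was not called (5, 2 and 0 adjusted over the list alone; adjusted p = 0.729). CER1, a secreted Nodal and BMP antagonist, was at 7.42 ± 0.676 TPM and listed at 0 in both pEF libraries, whereas PDGFRA and NID2 were lower in pgEpiSC (0.267 ± 0.0486 against 16.5 ± 1.66 and 0.262 ± 0.222 against 5.92 ± 3.89 TPM). Of 7 trophectoderm and amnion genes 3 rose, 2 fell and 2 were not called (5, 2 and 0 adjusted over the list alone; adjusted p = 0.279). Of the 3 that rose, the simple-epithelial keratin genes KRT8 and KRT18 were at 85.8 ± 55.9 and 58.3 ± 59.3 TPM; DAB2 and PTGS2 were lower in pgEpiSC. In the germline list 3 genes passed the filter, too few for a test, and 2 rose; KIT, a receptor tyrosine kinase and 1 of the 2, was at 10.3 ± 6.68 against 0.0206 ± 0.00987 TPM, and the other, DND1, lost its call with either pEF library left out (2.09 and 2.11). Of 5 neural genes 2 rose and 3 were not called (the same adjusted over the list alone; adjusted p = 0.279). Of 6 cartilage and bone genes 2 rose, COL9A1 among them (12.7 ± 6.54 TPM, listed at 0 in both pEF libraries), and 3 fell, SPP1 among them (0.0880 ± 0.0243 against 16.1 ± 9.67 TPM), with no call for the list (2 and 3 adjusted over the list alone; adjusted p = 0.140). With either pEF library left out, 1 hypoblast, 2 trophectoderm, 0 neural and 1 cartilage members were called higher by limma. Endothelial and blood or immune genes were near the floor: 1 and 0 passed the filter, and no library had more than 3.42 TPM of any endothelial or 0.875 TPM of any blood or immune gene.

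Of 3 signalling lists, those of the Nodal pathway and of WNT targets and inhibitors were called lower as deposited. That of FGF receptors and ERK feedback was not called. Of 19 tested genes of the Nodal, activin and BMP pathway, 4 rose, 7 fell and 8 were not called (the same adjusted over the list alone), and the list was called lower (relative median -0.79, adjusted p = 0.0247; adjusted p = 0.662 with an estimated correlation). That call was lost after scaling (adjusted p = 0.139) and without pgEpiSC replicate 1, 2 or 3 (relative medians -0.83, -0.67 and -0.78). LEFTY2 and GDF3 were among those that rose; TGFBR2, a receptor of the TGF-beta arm, and ID3, a target of the BMP arm, fell, with log2 folds of -3.28 ± 0.53 and -3.09 ± 0.48. Without pEF replicate 1 or 2 the fold of GDF3 was 2.56 and 2.56 and not called. Of 9 tested WNT pathway targets and inhibitors 6 fell and 3 were not called, the same adjusted over the list alone. The relative median was -2.33 (camera, adjusted p = 0.000271 with the preset correlation and 0.327 with an estimated one). The 6 were WNT5A, WNT5B, DKK2, DKK3 and the secreted WNT antagonists SFRP1 and SFRP2. The list mixes targets with inhibitors, so its call gives no direction for the activity of the pathway. Among the members that fell, WNT5A was at 0.546 ± 0.366 against 17.7 ± 13.2 TPM and DKK2 at 0.0480 ± 0.00206 against 6.69 ± 6.59 TPM. FGF receptors and ERK feedback genes were not called as a list (3 rose, 2 fell, 14 not called, with 5 and 2 adjusted over the list alone, camera adjusted p = 0.872). After scaling 7 members were higher and 3 lower. Of those that rose, DUSP4 was at 10.5 ± 6.72 against 1.39 ± 0.933 TPM. FGF17 was at 3.46 ± 1.33 TPM and listed at 0 in both pEF libraries. Of the 2 that fell, IER3, an immediate early gene, was at 0.149 ± 0.0947 against 39.6 ± 0.165 TPM. Without pEF replicate 1 or 2, 1 and 1 Nodal and 0 and 0 FGF members were higher and 4 and 3 WNT and 1 and 2 FGF members were lower; 5 FGF members were higher without pgEpiSC replicate 1 or 4.

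Regulators of DNA methylation were higher in pgEpiSC: 6 of 11 rose, 0 fell and 5 were not called (6 higher and 1 lower adjusted over the list alone; relative median 1.27, adjusted p = 0.00943; adjusted p = 0.662 with an estimated correlation). HELLS, a chromatin remodeller needed for DNA methylation, was at 34.6 ± 10.9 against 0.760 ± 0.309 TPM, beside DNMT3B. DNMT1 and DNMT3A, at 14.2 ± 8.63 and 10.1 ± 6.73 TPM in pgEpiSC, lost their calls without pEF replicate 1 (folds 1.36 and 1.61) and without replicate 2 (2.37 and 2.22), and DNMT1 without pgEpiSC replicate 3 (1.75). Of 19 Polycomb and chromatin genes 6 rose and 13 were not called (the same adjusted over the list alone; list not called, adjusted p = 0.191); the Polycomb cofactor MTF2 was at 17.9 ± 5.73 against 2.63 ± 0.566 TPM, a call lost without pEF replicate 1 (2.18). Without pEF replicate 1 or 2, 2 and 3 DNA methylation and 0 and 2 Polycomb members were called higher, and without pgEpiSC replicate 2, 1 DNA methylation member was called lower. After scaling 8 Polycomb and chromatin genes were called higher and 5 lower, with that list still not called (camera adjusted p = 0.271). Among 11 imprinted genes PEG10, PHLDA2 and SGCE fell and 8 were not called (the same adjusted over the list alone), with PEG10 at 1.45 ± 1.33 against 46.1 ± 26.2 TPM. The list was called lower (adjusted p = 0.0393; adjusted p = 0.667 with an estimated correlation), with a median fold of 0.19, -0.29 relative to all genes, and a mean of -0.80; the call was lost after scaling (adjusted p = 0.237) and with either pEF library left out (relative medians -0.33 and -0.23).

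Proliferation genes were higher and p53 and senescence genes lower in pgEpiSC. Of 23 cell cycle and DNA replication genes, 18 rose, 3 fell and 2 were not called (the same adjusted over the list alone; relative median 1.70, adjusted p = 6.76e-05; adjusted p = 0.662 with an estimated correlation). Cyclin B1 (CCNB1) was at 41.5 ± 13.4 against 3.20 ± 2.91 TPM and topoisomerase TOP2A at 48.5 ± 14.5 against 4.91 ± 3.87 TPM. The genes that fell were D-type cyclins, which couple growth factor signals to the cell cycle, with CCND1 at 3.57 ± 2.82 against 14.99 ± 2.86 TPM and CCND2 at 3.06 ± 3.20 against 11.1 ± 5.25 TPM. CCND1 and CCND2 lost their calls without pEF replicate 1 (-1.81 and -2.23) or 2 (-2.17 and -1.31), and CCND2 without pgEpiSC replicate 3 (-1.64) or 4 (-1.52). Of 18 p53 target and senescence genes, 12 fell, 1 rose and 5 were not called (the same adjusted over the list alone; relative median -2.30, adjusted p = 8.46e-10; adjusted p = 0.285 with an estimated correlation). CDKN1A (p21), an inhibitor of cyclin-dependent kinases, was at 10.2 ± 15.4 against 185 ± 59.04 TPM, and the secreted factors IGFBP7, IL6 and CXCL8 had folds of -5.87 ± 0.52, -3.83 ± 0.52 and -6.29 ± 0.57. Without pEF replicate 1 or 2, 4 and 9 cell cycle members were higher and 0 and 0 lower, and 9 and 7 p53 members were lower; without pgEpiSC replicate 3 or 4, 1 cell cycle member was lower. TP53I3 was the p53 member that rose (2.37 ± 0.56), a call lost without pEF replicate 1 (2.33) or 2 (2.41).

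Nuclear genes of oxidative phosphorylation were higher in pgEpiSC, and the list of glycolytic genes was not called as deposited. Of 24 oxidative phosphorylation genes 14 rose and 10 were not called (15 and 9 adjusted over the list alone; relative median 0.97, adjusted p = 0.000147; adjusted p = 0.662 with an estimated correlation). Cytochrome c (CYCS) was at 149 ± 14.8 against 36.3 ± 2.39 TPM and the complex III subunit UQCRFS1 at 98.02 ± 20.02 against 19.6 ± 2.22 TPM. After scaling 9 members were called higher, and without pEF replicate 1 or 2 as deposited 2 and 8; without pgEpiSC replicate 3, 9 were. The pgEpiSC libraries also differed in this list, with median deviations from their own mean after scaling of 0.43, -0.29, -0.47 and 0.38 log2 units in libraries 1 to 4. Of 17 glycolytic genes 2 fell and 15 were not called (the same adjusted over the list alone, relative median -0.68, camera adjusted p = 0.0644). After scaling 7 were called lower, 0 higher and 10 were not called, with the list still not called (camera adjusted p = 0.0611). LDHA, which converts pyruvate to lactate, was at 74.5 ± 56.9 against 271 ± 119.8 TPM, at 356 in pEF 1 and 186 in pEF 2; its call was lost without pEF replicate 1 (-1.72) or 2 (-2.65). The list was called lower without pgEpiSC replicate 2 or 3 and without pEF replicate 2 (relative medians -0.91, -0.77 and -1.03). The relative median was -0.21 without pEF replicate 1 (adjusted p = 0.532), and the median member was 0.94 log2 units higher in pEF 1 than in pEF 2 after scaling. Members lower numbered 6 without pgEpiSC replicate 2 and 0 with either pEF library left out, by limma.

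Interferon response and antigen presentation genes were lower in pgEpiSC, and the 2 pEF libraries differed from each other in them. Of 20 tested genes 16 fell, 0 rose and 4 were not called (18, 0 and 2 adjusted over the list alone; relative median -2.85, adjusted p = 2.81e-16; adjusted p = 0.285 with an estimated correlation). The interferon-induced genes IFI6, IFIT1, ISG15 and MX1 averaged 5.14, 0.303, 0.511 and 2.37 TPM in pgEpiSC. They were at 341, 112, 65.4 and 91.6 TPM in pEF 1 and at 28.5, 11.3, 6.16 and 22.4 TPM in pEF 2. Without pEF replicate 1 the list remained called lower (relative median -1.70, 11 members called), IFI6 and MX1 lost their calls (folds -2.42 and -3.06), and IFIT1 and ISG15 kept theirs. Among 8 immediate early and heat shock genes 2 fell and 6 were not called (the same adjusted over the list alone; relative median -0.93, adjusted p = 0.0281; adjusted p = 0.636 with an estimated correlation); JUNB, a subunit of the AP-1 transcription factor, was listed at 0 in all 4 pgEpiSC libraries and at 19.02 and 26.9 TPM in pEF. This list's call was lost after scaling (adjusted p = 0.0751) and without pgEpiSC replicate 2 (relative median -0.82), and 1 member was called lower without pgEpiSC replicate 3 or either pEF replicate.

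Replicates were closer to one another than the groups were. Across genes, Pearson correlations of log2(TPM + 1) were 0.935 to 0.990 between pgEpiSC libraries, 0.956 between the pEF libraries and 0.608 to 0.660 between groups; genes are not independent replicates. The median gene SD was 0.589 log2 units in pgEpiSC and 0.339 in pEF as deposited and 0.220 and 0.135 after scaling. The first principal component held 67.2% of the variance as deposited and 84.5% after scaling and parted the 2 groups in both. With 2 pEF libraries, 16 of 25 tested lists were called by camera with a preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.112); fry, which asks whether members move on balance in 1 direction, called 10. Those were 9 of the 16 and the primitive streak and mesoderm list (adjusted p = 0.0484), which camera did not call. Called by camera and not by fry were the lists of formative and primed epiblast (0.0710), epithelial junction (0.0567), Nodal, activin and BMP (0.395), DNA methylation (0.0567), cell cycle (0.0756), imprinted (0.252) and immediate early genes (0.0812). Of the 16, 13 were also called after scaling.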

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

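No explanation of these values was tested. A total of 6 values among the 4 pgEpiSC libraries had a gap between 1 library and the nearest other that exceeded Dixon's 95% critical value. The gap was taken as a share of their whole range (the ratio below). For genes the ratio was computed on the log2(TPM + 1) scale, whereas the values printed below are TPM. In all 165 values were examined, of which chance alone would give about 8.2 at 1 in 20. CXCL8 (ratio 1) was at 0.0141 TPM in pgEpiSC 1 and listed at 0 in the others. KLF17 (ratio 1) was at 0.0197 TPM in pgEpiSC 3 and listed at 0 in the others. GBX2 (0.912) was at 0.207 TPM in pgEpiSC 2 and at 0.00804, 0.0242 and 0.0163 TPM in libraries 1, 3 and 4. HOXA9 (0.944) was at 0.0709 TPM in pgEpiSC 4 and at 0.00889, 0.00699 and 0.0104 TPM in libraries 1 to 3. IL6 (0.971) was at 0.183 TPM in pgEpiSC 3 and at 0.0150, 0.0196 and 0.0194 TPM in libraries 1, 2 and 4. TFAM (0.848) was at 31.2 TPM in pgEpiSC 2 and at 16.8, 16.9 and 18.5 TPM in libraries 1, 3 and 4. The 5 other than TFAM lie below 1 TPM in every pgEpiSC library.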

How the results depend on the processing

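Median-ratio scaling combined with a left-out library, with the replicate block or with an estimated correlation, and scaled detection counts, were chosen after seeing the data. The causes of the changes below were not tested unless stated. Of 3005 values for 122 named genes, 2769 kept direction and side of the threshold, 194 lost the call, 40 gained it and 2 reversed; of 662 values for 25 lists the numbers were 568, 74, 13 and 7. The library weights came from an iteration that stopped before its tolerance was met. Leaving out a pEF library leaves 1, which is assumed to vary like the other group. Depth is unknown and its limit was not analysed here.

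Genes higher (1874) numbered 967 with a pseudocount of 5, 787 with no filter, 1185 with a filter of mean TPM 5, 3374 after quantile normalization, and 252 to 2270 with 1 library left out; scaled without pgEpiSC replicate 2, 2896. Genes lower (983) numbered 368 with a filter of mean TPM 5, 3222 after median-ratio scaling, 2924 rescaled to 1000000, 2779 after quantile normalization, 2879 without histone and ribosomal protein genes, 1616 with library weights, and 555 to 1367 with 1 library left out; scaled with pgEpiSC 1 to 4 and pEF 1 and 2 left out in turn, 2953, 3327, 3014, 3018, 2686 and 2664. The stricter filter tests fewer genes. Genes higher by at least 1 log2 unit (1836) numbered 874, 759 and 1182 with a pseudocount of 5, no filter and mean TPM 5, 252 to 2213 with 1 library left out, and 1155 scaled without pEF replicate 1. Genes lower by at least 1 log2 unit (974) numbered 501 with a pseudocount of 5, 368 with mean TPM 5, 2032 scaled, 2705 rescaled to 1000000, 1699 after quantile normalization, 2624 without histone and ribosomal protein genes, 1505 with library weights, 539 to 1355 with 1 library left out, and, scaled with each left out in the same order, 2034, 2040, 1990, 2037, 1973 and 2014.

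Some replicate numbers were shared by the groups. The other numbers occurred in pgEpiSC alone, so with the replicate block the group difference rests on the 2 same-numbered pairs. That fit leaves 1 residual degree of freedom. The 2 pairs deviated together weakly (r across genes 0.0982 and 0.172; 0.0671 and 0.113 after scaling), and pgEpiSC 4 with pEF 1, which share no number, reached 0.142 and 0.131, so the replicate block is given only here. With the replicate block 2204 genes were higher and 893 lower; scaled with the replicate block 2304 were higher and 2619 lower, 1983 of the lower ones by at least 1 log2 unit. With the block the relative median of Nodal genes was -0.88 and of immediate early genes -0.65 (calls lost), and of trophectoderm genes 0.93 (now called); scaled with the block Nodal was -1.01, imprinted -0.30 and immediate early -0.61 (calls lost).

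With an estimated correlation 0 lists were called by camera (16 with the preset one); the relative medians are unchanged by construction and are given as deposited and scaled: core pluripotency 2.55 and 2.79, formative and primed 1.11 and 1.21, fibroblast -4.50 and -4.40, mesenchymal -2.93 and -2.82, contractile -5.54 and -5.70, epithelial 2.30 and 2.36, HOX -1.85 and -1.66, WNT -2.33 and -2.46, Nodal -0.79 and -0.77, DNA methylation 1.27 and 1.28, cell cycle 1.70 and 1.80, p53 -2.30 and -2.32, oxidative phosphorylation 0.97 and 0.81, interferon -2.85 and -2.82, imprinted -0.29 and -0.43, and immediate early -0.93 and -0.90.

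With no filter the relative medians turned sign for naive (0.0149), hypoblast (-0.0629), trophectoderm (-0.0856), neural (-0.0985), imprinted (0.0863) and cartilage genes (0.0594), and the formative and primed list (1.16) lost its call; this setting adds genes near 0. FGF genes turned with mean TPM 5 (-0.31). Streak genes were called after rescaling to 1000000 (2.86) and without histone and ribosomal protein genes (2.97), and trophectoderm genes with a pseudocount of 0.1 (1.82). WNT genes lost the call scaled without pgEpiSC replicate 2 (-2.44). The Nodal call was lost with a pseudocount of 0.1 (-1.08), scaled (-0.77), rescaled to 1000000 (-1.04), after quantile normalization (-0.86), without histone and ribosomal protein genes (-1.05), with library weights (-0.73), and scaled without pgEpiSC 1 to 4 (-0.70, -0.74, -0.85 and -0.88) or pEF 2 (-0.65); its range with 1 library left out was -1.13 to -0.67. Glycolysis genes were called with mean TPM 5 (-1.11), rescaled to 1000000 (-0.89), without histone and ribosomal protein genes (-0.89), with library weights (-0.95) and scaled without pgEpiSC 2 (-1.01) or pEF 2 (-1.33), with a range of -1.03 to -0.21 with 1 library left out. The imprinted call was lost scaled (-0.43), rescaled to 1000000 (-0.48), after quantile normalization (-0.32), without histone and ribosomal protein genes (-0.47) and scaled without pgEpiSC 1 to 4 and pEF 1 and 2 (-0.35, -0.44, -0.38, -0.38, -0.37 and -0.43), with a range of -0.45 to -0.18. The immediate early call was lost scaled (-0.90), after quantile normalization (-0.84), with library weights (-0.75) and scaled without pgEpiSC 2 to 4 (-0.82, -0.77 and -0.84) and pEF 1 and 2 (-1.20 and -0.60), with a range of -1.25 to -0.59. RPS28 turned after quantile normalization (-0.63) and scaled without pgEpiSC 1 (-0.0056). The difference in genes detected (655.75) was -476.5 after scaling and ran from -89.75 to 1401 with 1 library left out.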

Other observations

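The families below and all tests of explanations but that of correlations after quantile normalization were chosen only after the result was seen. Families of genes that share a symbol stem, with at least 10 tested members, add to the comparison of pgEpiSC with pEF. Of 93 families, camera with a preset correlation called 9, of which 4 were also called after scaling and 0 with an estimated correlation (adjusted p = 1 for each). Collagen genes fell (2 higher, 14 lower, 2 not called; relative median -4.07, adjusted p = 4.51e-16), and nucleoporins (13, 0 and 8; 1.12, adjusted p = 0.00375) and SR splicing factors (7, 0 and 3; 1.52, adjusted p = 0.00454) rose. The KLF family was called lower (-1.56, adjusted p = 0.0343) with 4 of its 12 tested members lower and 8 not called. The RPL, RPS, PDE, LSM and MRPL families were called as deposited and not after scaling.

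Interferon response genes were far higher in pEF 1 than in pEF 2 (IFI6 341 against 28.5 TPM, IFIT1 112 against 11.3 TPM). Immune or blood cells in pEF 1 would bring their own transcripts, but the highest blood or immune gene there was at 0.129 TPM, which speaks against them. Overall scale is also excluded as the whole cause, since the median log2 difference of the tested members after median-ratio scaling was 2.45, and so are a few extreme members, since 20 of 20 were higher in pEF 1. Glycolysis genes were also higher in pEF 1 (median 0.94), and contractile (-0.87) and cell cycle genes (-0.48) lower. The labels give nothing that separates the 2 pEF libraries, and no biological explanation was tested.

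Libraries 1 and 4 of pgEpiSC were closer to each other (r across genes 0.990) than to libraries 2 and 3. The median absolute log2 difference between 1 and 4 was 0.241 times the smallest of any other pair as deposited and 0.506 times after median-ratio scaling (SD 0.00779 over 200 resamples of genes), so scale carried part of the split and was excluded as the whole cause; it was 0.565 times after quantile normalization. By correlation, 1 and 4 exceeded the highest other pair by 0.0229 after scaling, a measure that hardly responds to scale. The deviation of each library rose with level in libraries 1 and 4 (rank correlations 0.408 and 0.395, across genes) and fell in 2 and 3 (-0.191 and -0.546), the same split. Quantile normalization took those rank correlations to between -0.0198 and 0.0236. It left an excess of 0.023 (SD 0.000981 over 200 resamples of genes), above the 0.02 set beforehand. That limit was set to exclude the trend as the whole cause. Taking out the median deviation at each level, a correction added later, left 0.0167, below that limit. Part of the excess may thus go with level, and whether level is excluded as the whole cause depends on the correction. Resampling genes measures no spread between libraries. A trend with the genomic span of genes was predicted to give libraries 2 and 3 the same sign. The rank correlation of the deviation with span was 0.348 in library 3 and -0.158 in library 2, across genes. It was -0.0683 in library 1 and -0.0694 in library 4. Such a trend could leave 1 and 4 alike while moving 2 and 3 apart, so the opposite signs do not decide whether span contributes. Oxidative phosphorylation genes followed the same split, with median deviations of 0.43 and 0.38 log2 units in libraries 1 and 4 and -0.29 and -0.47 in 2 and 3. No biological explanation was tested.

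Genes with no symbol held a larger share of the listed TPM in pgEpiSC. Near-identical copies that share reads may contribute, as unnamed rows with the same TPM as another row in all 6 libraries held 4.34% of the unnamed TPM in pgEpiSC, a value that neither fits nor excludes that explanation. Whether a few abundant rows make the difference was not settled: without the 25 rows with the largest excess, which held 25.1% of the TPM in pgEpiSC and 7.49% in pEF, the shares were 21.1 and 16.8%, 4.31 points apart, but the 25 were picked by that excess, so the difference had to shrink. Of 1507 tested genes with no symbol 409 rose and 127 fell. No biological explanation was tested.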
